A study of Zea mays with 6 samples.

How the data were processed

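The material was the third leaf of the maize inbred line B73, grown with 16 h of light at 25 °C and 8 h of darkness at 20 °C under 130 µmol photons m-2 s-1 and harvested 13 to 14 days after sowing. Per the labels' protocols, the maturing zone was a 4 cm piece from the middle of the illuminated blade, and the base was the lowest 1 to 2 cm of the same leaves, which light did not reach. RNA came from pools of 6 plants per replicate and chromatin from pools of 10 plants per replicate. Transcripts were read by poly(A) RNA sequencing with 50 bp single-end reads, and 2 histone marks, acetylation of lysine 9 on histone H3 (H3K9ac) and trimethylation of lysine 4 on histone H3 (H3K4me3), were read by chromatin immunoprecipitation and sequencing (ChIP-seq).

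The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.32, DiffBind 1.10.0, edgeR and the B73 RefGen_v3 build, without saying which step used which. The aligner, the read counter and the peak caller are not given in the sources used here. The RNA table holds whole-number read counts over exons, per the file headers, for 110149 gene features in 4 libraries, with replicates A and B of each zone. It also holds RPKM values that the authors computed per library, which served here only to derive a relative exon length per gene. For each transcript the deposited table gives a signed fold change and an FDR-corrected p-value. The ChIP tables hold, per region, the authors' average normalized read signal in each zone, a signed fold change and an FDR-corrected p-value, per the file headers. The headers write the fold as base over maturing zone, yet positive folds went with higher averages in the maturing zone, and the size of the fold matched the ratio of the averages to within 0.007 on the log2 scale. How the averages were scaled, how many ChIP replicates they cover and how deep those libraries were is not given in the sources used here, so no standard deviation or depth stands beside them.

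The RNA libraries held 44243772 (base A), 24205348 (base B), 50657759 (maturing zone A) and 18325106 (maturing zone B) exon reads. Intervals and floors given for reads cover counting error only, because the reads carry no molecular identifiers. Kit strandedness is not given in the sources used here, so reads from overlapping or antisense genes, and from near-identical copies such as histone, ribosomal protein and Rubisco small subunit genes, may be shared between features.

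Transcript levels were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 26787, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood test was run without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Differences are maturing zone minus base on the log2 scale, with standard errors taken from the size of the change and its F statistic. No test was refitted on the ChIP regions, since their table holds no values per replicate: calls are those of the authors' deposited table at its FDR under 0.05, and gained or lost means higher or lower in the maturing zone.

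The main fit did not pair libraries. In a second fit, same-lettered libraries were treated as pairs. The basis is the label statement that base pieces came from the same leaves, although the labels do not state that a letter marks the same pool in both zones, and this choice was written down after the counts of the blocked fit had been seen. The differences of A from B correlated between the zones with Pearson's r = 0.803 across 26787 genes, which are not independent replicates. A fit with the letter as a block stands beside the unblocked one where it changes a call or moves a count by over 1.5 times.

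The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, 5 times for each setting. With 200 changed genes the unblocked fit made 0 false calls among 32, and recovered 0% of 4-fold and 9.7% of 16-fold changes. With 8000 changed genes it recovered 21% of 4-fold and 86.5% of 16-fold changes, and 2.9% of its calls were false. For this fit the simulated libraries were independent, without the difference of A from B that the real libraries share between zones. Its recovered and false shares may therefore differ in these data. The blocked fit recovered 93.1% of 4-fold changes with 200 changed genes, but 16.5% of its calls were then false, above the intended 5 in 100; with 8000 changed genes 3.9% were false. The set test called a simulated set of 30 genes raised 4-fold, and 2 of 100 unchanged sets fell under 0.05. Simulated genes varied independently of each other, whereas the photosystem list had an estimated correlation of 0.719. The share of 2 in 100 therefore does not measure false calls for lists whose members vary together.

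Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation beside it. With an estimated correlation camera uses the residual degrees of freedom of the fit, 2 without the block and 1 with it. That form therefore has little power here. Its p-values alone do not show whether correlation among members matters. The list themes, the list members given by gene identifier (36), the test designs and most alternatives were fixed before the data were examined; alternatives added later are named as such where they are reported. Members meant to be found by description keywords had to be chosen by gene symbol (182 further genes), because the reference table of the Zm-B73-REFERENCE-NAM-5.0 assembly pairs identifiers with symbols and not with descriptions; this was done after the tables were read and before any test. Of the 110149 features, 18985 matched that table and 2829 carried a gene name. A list for chlorophyll synthesis was not filled for the same reason, and the 3 plastid ribosomal protein members did not pass the count filter. No coordinates were taken from that assembly. Results for 1 gene of the meristem list are not reported here.

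The named genes follow a rule fixed at the same time: all identifier-given members of the C4 cycle, Calvin cycle, regulator and meristem lists; up to 4 members with the smallest adjusted p per symbol-chosen list; the 10 largest increases and 10 largest decreases among called genes with non-overlapping replicates and upper-half expression, named genes first; and per mark the 5 largest gains and losses and the called regions at C4 cycle genes.

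For relations between marks and transcripts, each gene was given its region with the highest mean signal, from the authors' assignment of a next gene to each region. The plan had been the nearest region, but the tables give no distances. Spearman's rho was tested with 100000 permutations, and gained against lost was set against higher against lower with Fisher's exact test, two-sided. Marks were paired where regions overlapped by at least 1 bp. The position of changed regions relative to gene starts was not analysed here, since no annotation of the same build was used. These steps ran in Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6, and were checked on simulated pairs and intervals. Alternatives covered the threshold, DESeq2 1.42.0 size factors and test, library totals, no count filter, the block and each library left out in turn. With 1 library left out the letters were unbalanced between the zones, so the difference of A from B entered the zone difference.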

Results

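A maize leaf grows from its base, so cells near the base are young and cells of the illuminated blade have matured and carry out C4 photosynthesis, in which mesophyll cells first fix CO2 into 4-carbon acids and bundle sheath cells release it to Rubisco. Transcripts, H3K9ac and H3K4me3 were each measured in both zones of the third leaf, giving 6 samples in 6 groups. The transcript table separates 2 replicate libraries per zone, with 18325106 to 50657759 exon reads each; the ChIP tables give authors' averages per zone over 43734 H3K9ac and 32908 H3K4me3 regions. The labels describe each replicate as its own pool of plants.

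The transcript comparison asked which genes differ between the mature and the young zone. Most enzymes of the C4 cycle rose. PEP carboxylase (PEPC, GRMZM2G083841), which makes the first C4 acid, stood at 8.33 and 9.21 TMM-scaled CPM in base libraries A and B and at 9504 and 13900 in the maturing zone, a log2 difference of 10.38 ± 1.58 (SE, n = 2 libraries per zone; edgeR adjusted p = 0.0147). Pyruvate orthophosphate dikinase (PPDK, GRMZM2G306345), which regenerates PEP, rose by 9.71 ± 2.30, the bundle sheath decarboxylases NADP-ME (GRMZM2G085019) by 10.51 ± 1.99 and PEPCK (GRMZM2G001696) by 11.93 ± 2.35, and a carbonic anhydrase (GRMZM2G121878) by 11.00 ± 1.78 on the log2 scale. Without base library A the values of PEPCK and NADP-ME were 14.13 and 12.02, without base library B 11.08 and 9.76, and without maturing zone library B that of PEPCK was 10.90. Of 17 C4 cycle genes 15 rose, and 16 when adjusted over the list alone. PEPC kinase (PPCK1, GRMZM2G178074) differed by 3.20 ± 0.99 with an edgeR adjusted p of 0.0615, and by 3.02 ± 0.21 with an adjusted p of 4.94e-06 in the edgeR fit with the replicate block. It was called without base library B (0.00499), without maturing zone library A (0.000598), without a count filter (0.000353) and in the DESeq2 test (0.00125), and not called without base library A (0.0757), without maturing zone library B (1.66, 0.267), under library totals (1.93, 0.0966) or with DESeq2 size factors (0.0716). The aspartate aminotransferase AspAT (GRMZM2G146677) differed by -0.60 ± 0.48 with an adjusted p of 0.387, and by -0.62 ± 0.22 with 0.0333 in the blocked fit. Camera put the C4 list above the other genes (adjusted p = 4.95e-12), with adjusted p = 0.223 under an estimated correlation. The PPDK call was lost with DESeq2 size factors (edgeR adjusted p = 0.0544), and without base library A 12 of the 17 genes were called, with OMT1 transporter, DCT1 and the PEP/phosphate translocator GRMZM2G174107 no longer among them (0.0872, 0.0763 and 0.0613).

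**Figure D1:**
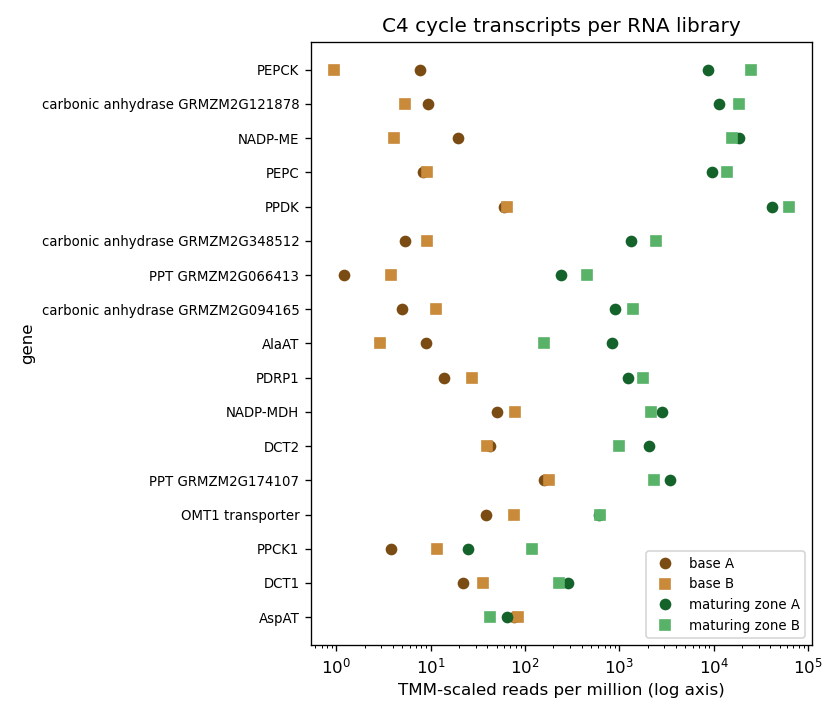
Expression of the 17 C4 cycle genes, with TMM-scaled CPM on a log axis and 1 point per RNA library (circles A, squares B). The maturing zone points of PEPC lie at 9504 and 13900 and its base points at 8.33 and 9.21, whereas the 4 points of AspAT lie between 43.1 and 85.1.

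All 6 Calvin cycle genes tested rose, also when adjusted over the list alone. The Rubisco small subunit RBCS1 (GRMZM2G098520) rose by 5.41 ± 1.48 (edgeR adjusted p = 0.0454), Rubisco activase RCA1 (GRMZM2G162200) by 7.11 ± 0.86 and phosphoribulokinase PRK (GRMZM2G026024) by 3.91 ± 0.66 on the log2 scale. Without base library B RBCS1 stood at 6.55, without base library A RBCS1 at 4.77 and RCA1 at 7.70. The RBCS1 call was lost with DESeq2 size factors (0.0628), without base library A (0.0728) and without maturing zone library A (0.0503). Of 19 photosystem and light-harvesting genes tested, 12 rose, 7 were not called, and 15 rose when adjusted over the list alone; the antenna proteins LHCB4 and LHCB5 rose by 6.30 ± 0.94 and 4.33 ± 0.77, and without base library B their values were 7.02 and 4.96. The blocked fit called 17 higher and 2 lower. Library totals gave 15 higher and 2 lower, and no count filter gave 18 higher and 1 lower of 21 tested. Camera adjusted p was 9.76e-06 for the Calvin list and 4.14e-08 for the photosystem list, and adjusted p = 0.258 and 0.413 with an estimated correlation.

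Among 6 regulators linked to photosynthetic cell types, golden2-like 1 (GLK1, GRMZM2G026833) rose by 5.19 ± 1.08 and golden2 (G2, GRMZM2G087804) by 3.17 ± 0.60 (edgeR adjusted p = 0.0243 and 0.0201); both are transcription factors of chloroplast development. GLK1 stood at 4.45 without base library A, 6.77 without base library B and 4.60 without maturing zone library B. Adjusted over the list alone, 2 genes rose as well. G2 was not called without base library A (adjusted p = 0.0622). SCR (GRMZM2G131516), a scarecrow gene, differed by -2.77 ± 1.11 with an edgeR adjusted p of 0.115 and by -3.02 ± 0.24 with 8.64e-06 in the blocked fit. It was called without base library A (0.00339), without maturing zone library B (0.00234), under library totals (0.0101), without a count filter (0.00084) and in the DESeq2 test (0.0242), and not called without base library B (-1.58, 0.244), without maturing zone library A (-1.90, 0.211) or with DESeq2 size factors (0.158). The other 3, a second scarecrow gene, short-root and DOF2, had adjusted p from 0.41 to 0.517; the blocked fit called all 3, and the signs of the second scarecrow gene and DOF2 turned under library totals and without maturing zone library B, and that of short-root without base library B. The second scarecrow gene was called without base library B (edgeR adjusted p = 0.0487). Camera gave adjusted p = 0.321 for this list.

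Most listed genes of dividing cells were lower in the maturing zone. Of 24 cell cycle and DNA replication genes tested, 18 fell (19 adjusted over the list alone); the replication helicase subunits MCM6 (GRMZM2G021069) and MCM7 (GRMZM2G065205) had 4775 and 4350 reads in base A against 2 and 5 in maturing zone A, with log2 differences of -8.89 ± 1.07 and -8.62 ± 0.75 (edgeR adjusted p = 0.013 for both). Of 9 core histone genes tested 8 fell, among them HIS2B5 with a log2 difference of -5.82 ± 0.92 (-5.11 without maturing zone library A and -7.00 without library B), and adjusted over the list alone 8 fell and 1 rose. Of 27 cytosolic ribosomal protein genes tested 19 fell and 1 rose (20 and 1 adjusted over the list alone), with RPP2A at -3.33 ± 0.51. MCM6 stood at -8.01 without base library A, -7.81 without maturing zone library A and -9.83 without maturing zone library B. The ribosomal count of 19 was 11 without base library A and 5 without either maturing zone library, and the count of 1 higher was 0 without each of the 4 libraries. The blocked fit called 22 cell cycle genes lower and 1 higher, 8 core histone genes lower and 1 higher, and 25 ribosomal protein genes lower and 2 higher. Camera adjusted p was 1.57e-09, 9.58e-05 and 3.75e-06 for the 3 lists in that order, and adjusted p = 0.231, 0.258 and 0.258 with an estimated correlation.

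Of 24 meristem, KNOX and growth-regulating factor genes tested, 7 fell and 0 rose, and the same counts passed when adjusted over the list alone; the blocked fit called 17 lower and 2 higher. Under library totals 13 of the 24 fell. Without a count filter, without base library B and without maturing zone library A 28 genes of the list were tested, of which 13, 11 and 4 fell. RS2 (GRMZM2G403620) differed by -5.53 ± 1.34 and a growth-regulating factor, GRF1 (GRMZM2G178261), by -5.65 ± 0.68 (edgeR adjusted p = 0.0341 and 0.013). RS2 ranged from -4.34 without base library B and -4.49 without maturing zone library A to -6.18 without base library A and -7.77 without maturing zone library B, where GRF1 stood at -6.31. The KNOX gene KNOX8 had 30 and 10 reads in base A and B and 0 in both maturing zone libraries, at least 6.35-fold lower against a floor of 3 reads over the zone. Its call was lost without maturing zone library A (edgeR adjusted p = 0.377), without library B (0.114) and in the DESeq2 test (0.109). LG3 had 138 and 9 reads in the base and 0 in the maturing zone, at least 23.3-fold lower, or at least 4.63-fold from base library B alone, with an edgeR adjusted p of 0.0556 and 0.000425 in the blocked fit. It was called without base library B (0.0022), without maturing zone library B (0.0384), under library totals (0.00782), without a count filter (0.000418) and in the DESeq2 test (0.005), and not called without maturing zone library A (0.153) or with DESeq2 size factors (0.0647). KN1 (knotted1) had 169 reads in base A, 2 in base B, 8 in maturing zone A and 6 in maturing zone B, with an adjusted p of 0.47. LG1 and LG2 differed by -4.38 ± 1.76 and 1.65 ± 0.62 with edgeR adjusted p of 0.116 and 0.101, and 0.000582 and 0.000112 in the blocked fit. LG1 was called without base library A (0.017), without maturing zone library B (0.00864), under library totals (0.0146), without a count filter (0.00225) and in the DESeq2 test (0.0101), and not called without base library B (0.0721), without maturing zone library A (-2.87, 0.289) or with DESeq2 size factors (0.149). LG4 and GN1 did not pass the count filter, with 89 and 39 reads in base A and 5 and 1 in base B. Camera gave adjusted p = 0.00951 for the list, 0.241 among genes above the median level, and 0.441 with an estimated correlation.

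Of 35 cell wall genes tested 14 fell and 1 rose (15 and 1 adjusted over the list alone). The beta-expansin EXPB8, a wall-loosening protein, and CAD1 differed by -5.19 ± 0.76 and -5.50 ± 0.75, while the xyloglucan endotransglucosylase XET1 rose by 9.36 ± 1.04 (edgeR adjusted p = 0.0142, 0.0136 and 0.013). Without base library B the values of EXPB8, CAD1 and XET1 were -4.42, -4.81 and 8.77, and XET1 stood at 10.93 without base library A and 8.61 without maturing zone library B. Without base library B and without maturing zone library A 2 cell wall genes rose. The blocked fit called 26 lower and 4 higher, and under library totals 24 fell. Of 17 histone-modifying enzyme genes tested 2 fell, the histone deacetylase HDT103 at -3.73 ± 0.78 and SDG118 at -2.25 ± 0.58 (edgeR adjusted p = 0.0246 and 0.0398), and 0 fell when adjusted over the list alone. The blocked fit called 10 lower and 4 higher. Under library totals and in the DESeq2 test 4 fell, and without a count filter 4 of 18 tested. Without base library B 4 fell, without base library A or maturing zone library B 1 fell, HDT103 stood at -3.02 without base library A and -4.55 without maturing zone library A, and SDG118 was not called without base library A, maturing zone library A or maturing zone library B (edgeR adjusted p = 0.215, 0.0962 and 0.189). Camera adjusted p was 0.000294 for the cell wall and 0.393 for the histone-modifying list, and adjusted p = 0.505 and 0.929 with an estimated correlation.

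Markers of the cell types in the leaf were counted as lists of their own. All 4 mesophyll and all 4 bundle sheath markers rose, also when adjusted over the list alone, and all of these are C4 or Calvin cycle genes already counted above; camera adjusted p was 3.75e-06 and 0.000166, and adjusted p = 0.231 for each with an estimated correlation. Of 5 vascular genes tested 1 rose (1 adjusted over the list alone), the sucrose transporter SUT1, by 6.53 ± 1.13, and 4 were not called. SUT1 stood at 5.91 without base library A, 7.59 without base library B and 5.85 without maturing zone library B. The blocked fit called 2 higher and 3 lower. Under library totals 3 vascular genes fell, in the DESeq2 test and without base library A 2, without maturing zone library B 1, and without a count filter 2 of 7 tested. Of 6 epidermis genes tested 1 rose, the wax gene GL1, by 7.97 ± 1.22, and 3 fell, led by LTP3 at -7.35 ± 1.53 (edgeR adjusted p = 0.0246). Adjusted over the list alone 2 rose and 3 fell, and the blocked fit called 3 higher and 3 lower. With base library B, maturing zone library A or maturing zone library B left out, 1 epidermis gene fell, and without base library B or maturing zone library A 2 rose, so that more rose than fell. GL1 and LTP3 stood at 9.09 and -6.51 without base library B, 8.67 and -6.42 without maturing zone library A and 6.77 and -9.72 without maturing zone library B, and GL1 at 7.32 without base library A. Camera adjusted p was 0.94 for the vascular and for the epidermis list.

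In all, 7834 of 26787 genes were called, 3605 higher and 4229 lower in the maturing zone, and every one had an absolute log2 difference of at least 1. The largest named increases beside the C4 and Calvin genes were bss1 (11.94 ± 1.94), the indole-3-glycerol phosphate lyase Igl (11.77 ± 1.75), ZCN26, with 1 read in the base and 2442 in the maturing zone (ratio 5130, 95% exact binomial interval 920 to 203000), and vignain (11.15, edgeR adjusted p = 0.013). Base reads of Igl were 23 and 0. Without base library A bss1 and vignain stood at 13.35 and 12.74, without base library B bss1, Igl and vignain at 11.22, 10.91 and 10.47, and bss1 at 12.57 and 10.67 without maturing zone library A and B. The largest named decreases included cyclin8, with 3379 reads in the base and 1 in the maturing zone (ratio 1610, 95% exact binomial interval 288 to 63500), and Rbl1, at -8.80 ± 1.63 with 0 and 4 reads in maturing zone libraries A and B (-7.10 without library A). The smallest edgeR adjusted p was 0.013, so 0 genes passed 0.01, against 11664 at an unadjusted p under 0.05 and 8117 with DESeq2 at an adjusted p under 0.01. With the replicate block 20363 genes were called, 9543 higher and 10820 lower, in a fit whose calls on simulated counts were 16.5% false with 200 changed genes and 3.9% false with 8000. Scaling by library totals moved the median log2 difference by -1.14 and turned the split into 2548 higher and 8300 lower, so directions here are relative to TMM scaling. Without maturing zone library A 3372 genes were higher and 2584 lower, which turned the majority from lower to higher. The authors' deposited table had 8370 transcripts at FDR under 0.05, of which 7069 were called here in the same direction and 0 in the opposite one.

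H3K9ac was compared to find regions whose acetylation differs between the zones. The largest gains on the B73 RefGen_v3 build included a region of PEPC on chromosome 9 from 62303432 to 62304170, where the authors' deposited table has 1.54 normalized reads in the base and 314.3 in the maturing zone, a 204.2-fold gain (deposited FDR 7.08e-93); the lowest H3K9ac average listed for the base was 1.1, so the largest folds rest on base values near it. The other 4 largest lay next to GRMZM2G528052 on chromosome 1 (58455895 to 58456450, 286.9-fold, and 58454345 to 58454875, 216.5-fold), AC195983.3_FG010 on chromosome 10 (132001191 to 132001762, 151.1-fold) and GRMZM2G086285 on chromosome 1 (181909627 to 181910247, 126.4-fold) in the authors' deposited table. The region next to GRMZM2G086285 lay close to the C4 cycle gene DCT2, whose H3K9ac region of highest signal spans 181906809 to 181907750. In the authors' deposited table the largest loss, 46.55-fold, lay on chromosome 8 from 32967881 to 32968646 next to GRMZM2G111998. Of 47 regions assigned to C4 cycle genes 36 gained, 5 lost and 6 were not called. PEPC had 4 gained regions, PPDK 5, of which the one on chromosome 6 from 146190802 to 146191333 gained 59.53-fold, and PEPCK 3, one of them 86.57-fold on chromosome 1 from 35749487 to 35750157, all from the authors' deposited table. The 5 lost C4 regions lay at DCT1 (2 regions), AlaAT, PPCK1 and OMT1 transporter, with deposited log2 changes of -0.90, -0.46, -1.91, -0.85 and -0.63. Overall the authors' deposited table called 29236 of 43734 regions, 14442 gained and 14794 lost.

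**Figure D2:**
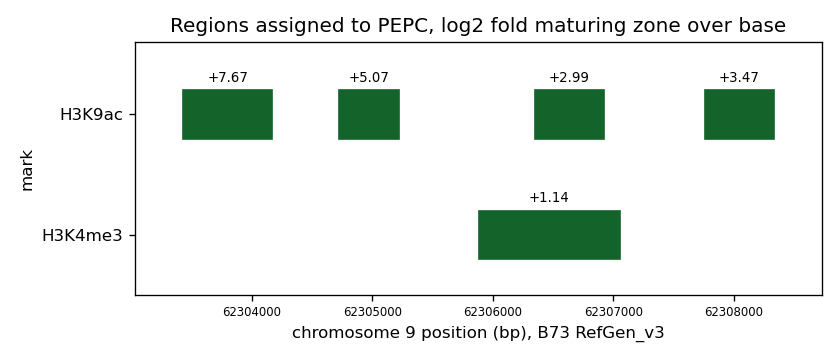
Regions assigned to PEPC along chromosome 9 of B73 RefGen_v3 (x axis, bp), 1 row per mark, with the deposited log2 fold of maturing zone over base above each box; green marks a gain. The 4 H3K9ac regions gained by 2.99 to 7.67 and the H3K4me3 region by 1.14.

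Among the tested genes of each list, the region of highest signal gained H3K9ac at 11 C4 cycle genes and lost it at 3, and gained it at 13 photosystem genes and lost it at 2. It lost H3K9ac at 15 cell cycle genes and gained it at 1, and lost it at 21 cell wall genes and gained it at 7. RS2 and GLK1 were picked here after their values had been seen. RS2 had 2 lost regions, of which that on chromosome 1 from 154971287 to 154972108 changed by -3.23 on the log2 scale in the authors' deposited table. The single GLK1 region, on chromosome 9 from 2713072 to 2713925, gained by 1.55.

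H3K4me3, a mark of transcribed promoters, was compared in the same way. The authors' deposited table called 8429 of 32908, 3733 gained and 4696 lost; the marks' calls come from separate tests, and their difference was not tested. The largest gain, 361.6-fold, lay next to GRMZM2G137535 on chromosome 6 (142504263 to 142505103), and the largest loss, 227.1-fold, next to GRMZM2G141386 on chromosome 1 (43770987 to 43771855) in that deposited table. The base average of GRMZM2G137535 and of the PPDK region with the largest fold was 1.5 normalized reads, the lowest listed and shared by 78 regions, so these folds and their ranks depend on that value. Of 22 regions at C4 cycle genes 10 gained, 0 lost and 12 were not called. PEPC had 1 region, which gained 2.21-fold (deposited FDR 0.0281), and PPDK had 3, which gained 90.34-fold, 51.3-fold and 2.17-fold. At cell cycle genes 22 of 30 regions lost the mark and 1 gained it. At cytosolic ribosomal protein genes 1 of 30 regions lost it and 29 were not called. Of 31 H3K9ac regions at the same list, 18 lost acetylation, 5 gained it and 8 were not called.

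Changes in both marks went with changes in transcript level. Across 21634 genes, which are not independent replicates, H3K9ac and transcript changes had a Spearman rho of 0.70, and across 20959 genes H3K4me3 and transcript changes had a rho of 0.702 (permutation p = 1e-05 for each, the smallest 100000 permutations can give; Benjamini-Hochberg adjusted 1e-05 over 3 relations). Of 5341 genes called for both H3K9ac and transcript, 2063 gained and rose, 3026 lost and fell, 105 gained and fell and 147 lost and rose. The odds ratio was 404 (95% interval 313 to 523, by a normal approximation on the log scale). For H3K4me3 the 3145 genes held 1249, 1853, 12 and 31 in the same order, an odds ratio of 6220 (3180 to 12200). The sizes of these odds ratios are not comparable between the marks, since 66.8% of H3K9ac but 25.6% of H3K4me3 regions were called. In 30433 overlapping pairs of regions the changes of the marks had a rho of 0.706 (permutation p = 1e-05), and 97.8% of 7078 pairs called in both changed in the same direction. With the replicate block in the transcript fit the odds ratios were 69.7 and 766.

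**Figure D3:**
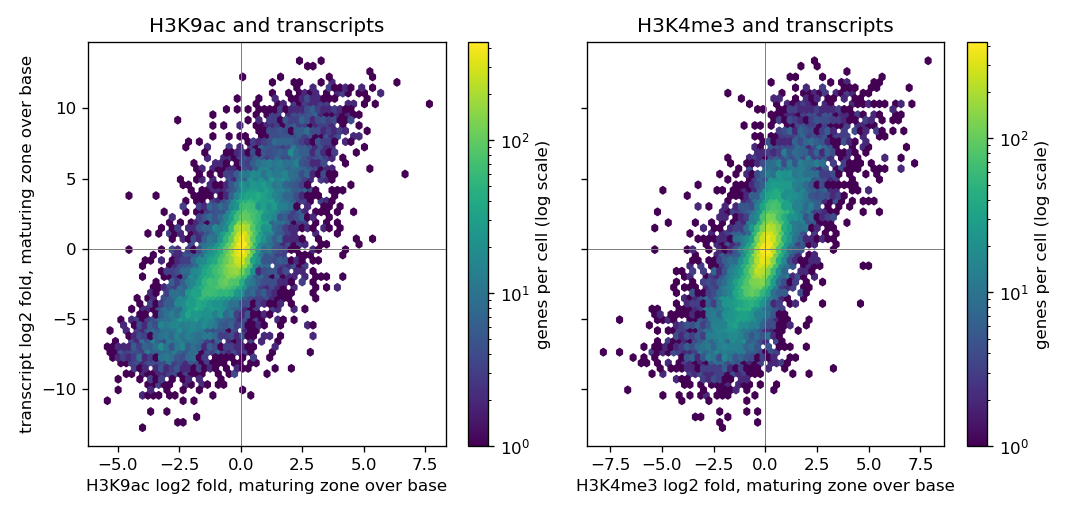
Log2 fold of each mark at a gene's region of highest signal (x axis) against the transcript log2 fold (y axis), maturing zone over base, with colour for genes per cell on a log scale. Both clouds run from lower left to upper right, with rho of 0.70 for H3K9ac and 0.702 for H3K4me3.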

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

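The test of KNOX reads against the shared difference between A and B was chosen after those reads had been seen, as had the reads of PCNA1, 1 of the 24 cell cycle genes used below. Reads appeared in genes that the count filter left out of the transcript comparison, with at least 100 reads in 1 library and at most 3 in each of the others, where a count of 0 allows 3. Such genes included CAB48 with 554 reads, GRMZM2G429938 with 440, GRMZM2G013798 with 135 and GRMZM2G374074 with 101, these 4 in maturing zone A.

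Reads of 4 class I KNOX genes were concentrated in 1 base library. KN1, LG3, LG4 and GN1 together had 435 reads in base A and 17 in base B, a scaled ratio of 11.41 (95% exact binomial interval 7.04 to 19.8), and 10 and 7 in the maturing zone. Further KNOX genes of the list had, unscaled in base A and B, 29 and 1 reads (KNOX3) and 913 and 394 (KNOX6). KNOX7 had 1146 and 510, and KNOX8 30 and 10. Base A was the deeper library, with 44243772 exon reads against 24205348. The unscaled reads of KNOX6 and KNOX7 therefore do not by themselves show a concentration. KNOX8 stood at 0.408 and 0.305 TMM-scaled CPM in base A and B, so it did not share the pattern. The shared difference of A from B stays open: the base ratio was 21.5 times the median of genes with a like difference in the maturing zone, but the test was set after the base reads had been seen, its matching rests on those few maturing zone reads, and 0.81% of tested genes had a base ratio above 7.04. More dividing tissue in base A cannot be told apart. The median log2 ratio of A over B for 24 cell cycle genes was 0.62 with a bootstrap interval from 0.06 to 1.3. Named core histone genes were mostly higher in base B. In base A and B, TMM-scaled CPM were 173 and 351 (H4 GRMZM2G084195), 158 and 283 (HIS2B5) and 45.5 and 79.4 (HIS2A1). H3 GRMZM2G401581 stood at 41.4 and 39.3. The core histone list as a whole was not called between A and B over both zones (camera adjusted p = 0.0902). Named cell cycle genes were higher in base A than in base B. Their values were 64.9 and 25.4 (MCM6), 59.1 and 34.8 (MCM7), 100.9 and 60.4 (KRP13) and 37.5 and 18.8 (cyclin8). Without base A 6608 genes were called.

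The RNA libraries A and B differed alike in both zones. With both zones in the model, 15786 of 26787 genes differed between A and B. Low counts and unequal depth are unlikely as the whole cause, since r between zones was 0.869 (0.863 to 0.874) in 7105 genes with a mean count of at least 1000. Gene length is also unlikely as the whole cause: the median A minus B in the base ran from -0.40 to 0.70 between the shortest and the longest of 10 length classes, but r was 0.795 after that trend was removed. Different plant pools or library handling stay open, because each zone has 1 library per letter. In camera tests of this difference the cell wall, photosystem, regulator and epidermis lists were higher in B (adjusted p = 0.000555, 0.00139, 0.00139 and 0.0192). The histone-modifying list was lower in B (camera adjusted p = 0.00072). With an estimated correlation the camera adjusted p was 0.784 for all of them. The blocked fit used there left 1 residual degree of freedom, so the value of 0.784 cannot show whether correlation accounts for these differences. Estimated correlations were -0.067, -0.067 and -0.059 for the regulator, epidermis and histone-modifying lists, and 0.789 and 0.341 for the photosystem and cell wall lists. No biological explanation was tested further.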

How the results depend on the processing

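Single-region genes, the blocked mark relations, the blocked list tests, the list counts without each library and the authors' calls on the same genes (8081) were alternatives chosen after the data had been seen. The transcript count of 7834 was 0 at an edgeR adjusted p under 0.01, where the smallest was 0.013. At an unadjusted p under 0.05 edgeR gave 11664 genes, and DESeq2 gave 8117 at an adjusted p under 0.01. With the replicate block the count was 20363, with the direction of all 7834 kept. On simulated counts the false share of the blocked fit was 16.5% with 200 changed genes and 3.9% with 8000. The block newly called 14 of 81 named genes and kept the calls of all 10 lists; among the named genes and the tests of lists and relations it changed no other call, while counts within lists moved. Leaving out 1 library gave 5956 to 7496 calls, with the lone library assumed to vary like the others. Without maturing zone library A 3372 were higher and 2584 lower, 56.6% higher against 46% with all 4 libraries. DESeq2 size factors gave 7295, the DESeq2 test 10517, library totals 10848 (2548 higher and 8300 lower) and no count filter 10879. H3K9ac calls fell from 29236 to 17412 with an absolute log2 fold of at least 1, and to 12109 (5228 gained and 6881 lost) among the 21867 regions above the median signal, 55.4% of those regions against 66.8% of all; H3K4me3 calls above its median were 2688, or 16.3% against 25.6% of all (8429). Of 10 lists called by camera, 0 were called with an estimated correlation (2 of 14 at an unadjusted p under 0.05), and the meristem list was not called among genes above the median level (adjusted p = 0.241). The estimated form had 2 residual degrees of freedom, so a loss of calls under it was likely whatever the correlation. For the C4 list the estimated correlation was -0.003, below the preset 0.01, yet the unadjusted camera p was 0.0159. A higher correlation was thus not the reason for that list. For the other lists, and for the meristem list above the median level, the cause was not tested. All alternatives run for the 3 relations kept their sign, with rho from 0.68 to 0.869. Shifts without a library include the difference of A from B, since the letters are then unbalanced between the zones. Of 726 alternative values for 81 named genes, 647 kept direction and side of the threshold, 53 passed it newly, 21 no longer passed and 5, all of uncalled genes, changed sign; 55 of 66 called genes stayed called throughout, and the fold of 45 moved by over 1.5 times without a library. Positions relative to gene starts, distance limits and regions upstream of genes were not run without a same-build annotation; pseudocounts did not apply, and refits, blocks and left-out replicates of the ChIP regions were not run because the table gives averages. No paired analysis was possible for the marks because their columns carry no replicate letters. ChIP depth is unknown, and the RNA depth of 18325106 to 50657759 reads limits KNOX genes with few reads.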

Other observations

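All comparisons in this part were chosen after the data had been seen. H3K9ac regions that overlap no H3K4me3 region behaved differently from the rest. Of 13512 such regions 79.8% were called in the authors' deposited table, against 61.1% of 30222 regions that overlap one. Of the called ones 63.2% gained acetylation in the maturing zone against 41.4%. The odds ratio was 2.43 (95% interval 2.32 to 2.56, by a normal approximation on the log scale), and regions are not independent. Within 10 classes of mean signal the odds ratio was 2.23 (2.09 to 2.37). Among the 47 regions at C4 cycle genes, 23 overlapped no H3K4me3 region, of which 18 gained and 2 lost acetylation, and of the other 24 regions 18 gained and 3 lost it. PEPC had 3 regions without H3K4me3, all gained.

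Lower signal may account for part of the higher share of calls. Median signal was 84.9 normalized reads without and 338.2 with an H3K4me3 region, and the odds ratio for being called fell from 2.51 to 1.29 (1.21 to 1.38) within 10 classes of mean signal, which leaves this open. The classes differed: called shares without and with an H3K4me3 region were 76.2% and 74.4% in the second lowest class, and 81.7% of 71 and 51.3% in the eighth. A location at other genes stays open as well. In 4390 genes with both kinds of region, the regions without H3K4me3 had the larger mean absolute change in 66.3% (exact interval 64.9 to 67.7). The larger change was thus also seen within genes. That test used the size of the change and not the share called, and it did not match regions by signal. Counting an H3K4me3 region within 1000 bp as shared gave an odds ratio for being called of 2.43, and of 1.27 (1.19 to 1.36) within the signal classes. No biological explanation was tested.

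The authors' deposited table lists 4 H3K9ac regions on the plastid chromosome, all called as gained by 2.42-fold to 4.00-fold, and 0 H3K4me3 regions there. Whether these reads reflect histone acetylation was not tested, so they are not read as a gain of the mark. At DCT1, AlaAT, OMT1 transporter and the Rubisco small subunit gene GRMZM2G113033, transcripts rose by 3.17, 6.40, 3.43 and 6.46 on the log2 scale. At each, a called H3K9ac region was lower in the maturing zone, by -0.90, -1.91, -0.63 and -0.49 in the authors' deposited table. The AlaAT region of highest signal is another one, which was not called (-0.23, deposited FDR 0.358).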
